A study of Medicago truncatula with 14 samples.

How the data were processed

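Chromatin immunoprecipitation sequencing was done on transformed Medicago truncatula roots (ecotype jemalong, cultivar Jester), with 3 NIN and 4 LSH1 immunoprecipitations and as many controls, 14 libraries in all. Per the labels, each library belongs to 1 construct, 1 role and 1 replicate number. The labels give the controls the same construct as the immunoprecipitations, while the labels' protocol also names a GFP construct with a nuclear localisation signal as control; which material the control libraries came from was left open. The labels do not say whether replicates were grown separately. P-values of the exact permutation and sign-flip tests over lists thus measure the spread between these lists, which may be technical. P-values from random placement, Fisher's exact tests and random gene lists rest on regions or genes and do not measure that spread.

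The deposited lists hold, per peak, a sequence name, a start, an end and a running number. They have no height, fold, p-value, q-value or summit. Per the submitters' processing notes, Bowtie2, Picard, MACS2 and ChIPseeker were used; the names of the lists give a q cutoff of 0.05 and narrow peaks, while versions, other settings and genome build are not given in the sources used here. Per the labels, the authors called peaks per replicate, from 1 immunoprecipitation and its control, and not on pooled samples. The running number follows the order of the list and not of the genome. Peak width correlated negatively with it in every list, with a Spearman rho of -0.522 to -0.324 in the LSH1 lists and NIN replicate 3. In NIN replicates 1 and 2 rho was only -0.0520 and -0.0893, so width gives little support there for an order by rank. The running number was read as a rank in all lists, by a measure that is not named. Percentile place is 100 times this number over the length of the list, so that low values are first. Read numbers per library were not analysed here, so the depth behind each list is unknown; a deeper library or a weaker control can give a longer list, and list lengths are not a measure of binding.

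Genes came from a RefSeq table of assembly MtrunA17r5.0-ANR with 39590 genes, of which 31728 coding genes lie on the 8 chromosomes. The sequence names of the peak lists begin with MtrunA17. LSH1 regions lay within 500 bp of a gene end in 28.0% of cases, and in 16.7 to 18.1% after the genes were moved by 1000, 5000 or 20000 bp to either side, so the 2 coordinate systems were used together. Gene coordinates are not printed; region coordinates are those of the lists, counted from 1. The table has no strand, product or exon structure, and no genome sequence was used. Exons, introns and untranslated regions at a peak are therefore not stated.

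The tests were fixed before the data were examined and were changed where the lists required it. Peak midpoints replaced summits, and the midpoint of the best-placed peak stood for a region. List order replaced −log10 q. Because strand is not given, the gene window ran from 2000 bp outside to 500 bp inside both gene ends instead of the start alone. A filter at −log10 q of at least 5, tests of 10 motifs and 15 gene lists by product name were not run. Nodulation genes were fixed by older gene identifiers; these are not in the table, so they were matched by symbol or synonym, which found 16 of 52. NIN, LSH1, LSH2, NF-YA1 and NF-YA2 were not matched and are not analysed here. Another 5 lists (nodulins and leghemoglobins, mycorrhizal symbiosis genes, lectins, lignin and saponin enzymes, hormone genes) were made from the symbols in the table after it had been seen and before their values were computed. The rule for named genes was NOOT1 and NOOT2 with all regions nearby, all target genes of the nodulation list, and the 10 best-placed target genes per protein and per set; genes without a known product could not be left out as the rule asked. Of the shared and protein-only sets only the first genes are named.

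Peaks of the lists of a protein that overlapped by at least 1 bp were merged, and merged regions with peaks of at least 2 lists were called reproducible. For random placement, each list or region set was moved 100 times to uniform positions on the same sequence with a fixed seed; the length of a sequence was taken as its last peak or gene end. The smallest p that this gives is 0.00990. Shares per list were compared between proteins with exact permutation tests over the 35 splits of 7 lists, whose smallest p is 0.0286. Target genes and gene lists were compared with two-sided Fisher's exact tests over coding genes, adjusted after Benjamini and Hochberg over 12 tests of 6 lists. Alternatives were peaks in all lists, the first 5000 peaks of each list, midpoints within 100 bp, an overlap of at least 50% of the smaller region, shifts of 20 to 100 kb in place of uniform placement, no regions over 2000 bp or on unplaced and organelle sequences, the Jaccard index, gene windows of 1000 bp and of the whole gene with 3000 bp to each side, 10000 random lists matched on gene length, and each list left out in turn.

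The functions were tested on simulated data of the real list lengths and widths for NIN against LSH1, over 31728 coding genes. With 2500 sites per protein, 500 of them shared, 100.0% of the sites were recovered for each protein and the overlap was 3.22 times that of random placement. Each simulated site was put in every list of its protein, so full recovery was built in. In 10 simulations without sites the ratio was 0.991 on average (0.854 to 1.13). Peaks in these simulations were spread uniformly, so a ratio near 1 was built in. The range does not hold for unrelated lists with the uneven spread of the real ones. Fewer than 7 lists were not simulated. Of random gene lists, 1.95% had a Fisher p under 0.05 in those simulations. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.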

Results

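The data were peak lists from chromatin immunoprecipitation followed by sequencing in transformed (hairy) roots of the legume Medicago truncatula, grown for 3 weeks under non-symbiotic conditions. The roots overexpressed a GFP fusion of NIN (NODULE INCEPTION, an RWP-RK transcription factor needed for nodule formation) or of LSH1 (a LIGHT SENSITIVE SHORT HYPOCOTYL protein of the ALOG family of transcriptional regulators) from a Lotus japonicus ubiquitin promoter. The stated purpose was to search for the binding sites of both proteins. The 14 libraries made 7 peak lists, 3 for NIN and 4 for LSH1, each from 1 immunoprecipitation and 1 control library of the same replicate number. The LSH1 lists held 25127, 21902, 18750 and 20787 peaks for replicates 1 to 4, a mean of 21642 ± 2665 (SD, n = 4). The NIN lists held 14021, 28825 and 84178 peaks for replicates 1 to 3, a mean of 42341 ± 36980 (SD, n = 3). The geometric mean of the NIN lists was 1.51 times that of the LSH1 lists, which is within the spread between lists (two-sided exact permutation test over 35 splits, p = 0.486). The list of NIN replicate 3 covered 52.7 Mb, against 4.04 and 9.13 Mb for the other NIN lists and 6.77 to 10.3 Mb for the LSH1 lists. Without it the ratio was 0.934.

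LSH1 peaks were found near the ends of coding genes more often than random positions, and NIN peaks less often. Midpoints of 45.5% ± 2.27 (SD, n = 4) of LSH1 peaks and 26.0% ± 1.71 (SD, n = 3) of NIN peaks lay within 2000 bp outside or 500 bp inside a gene end, against 31.8% of random positions. Within 500 bp of a gene end the shares were 24.7% ± 2.65 for LSH1 (SD, n = 4), 10.1% ± 0.728 for NIN (SD, n = 3) and 14.2% for random positions. More than 2000 bp from any coding gene lay 32.8% ± 1.87 of LSH1 peaks (SD, n = 4), 55.6% ± 4.49 of NIN peaks (SD, n = 3) and 46.8% of random positions. The shares of the 2 proteins did not overlap for any of these measures. Each difference had a two-sided exact permutation p of 0.0286, the smallest that 35 splits can give, and an adjusted p of 0.0429 (Benjamini-Hochberg over the 9 measures compared).

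**Figure D1:**
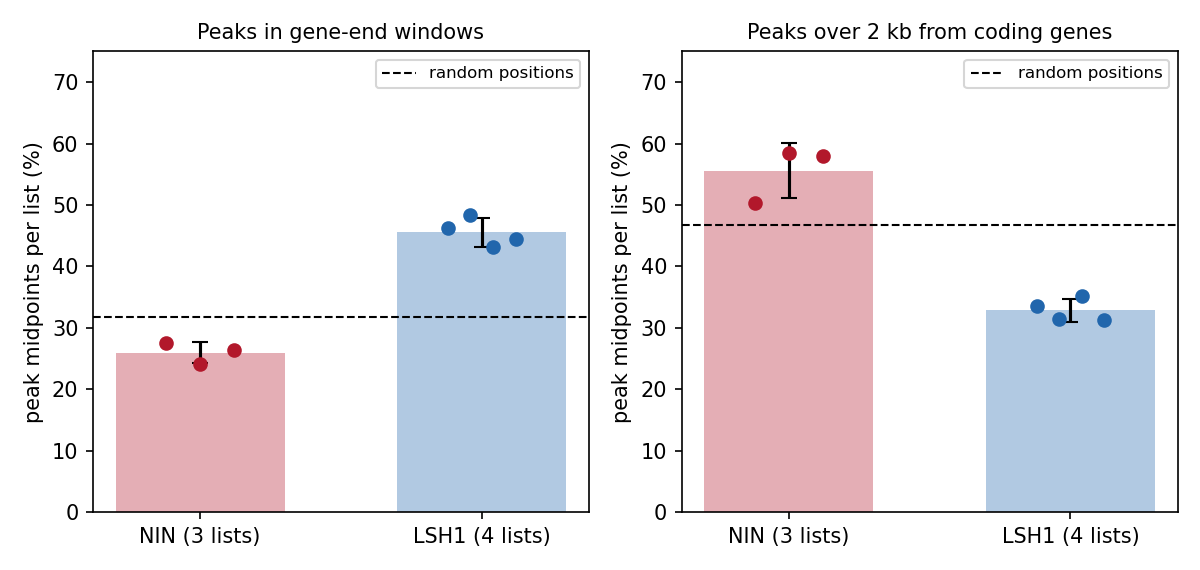
Share of peak midpoints (%) in windows at coding-gene ends (left) and over 2 kb from coding genes (right) for the NIN and LSH1 lists. Points are lists, bars are means with SD, and the dashed line is the share of random positions; the LSH1 lists lie at 43.1 to 48.4% on the left, above the line, and the NIN lists at 24.1 to 27.5%, below it.

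The 2 proteins also differed along the chromosomes. With each of the 8 chromosomes compared, 6 (1, 2, 3, 5, 6 and 8) had a two-sided exact permutation p of 0.0286, adjusted p = 0.0381 over the 8. The shares of a list add up to a fixed total, so these tests are not independent. Chromosome 6 was singled out after its values were seen, as the one where the means were furthest apart. This chromosome, which has 57.3 coding genes per Mb against 70 to 80.1 on the other chromosomes, held 12.4% ± 1.37 of NIN peaks (SD, n = 3) and 4.54% ± 0.607 of LSH1 peaks (SD, n = 4), while it makes up 10.1% of the chromosome length (exact permutation, adjusted p = 0.0429 over the 9 measures). Regions with peaks in at least 2 lists of a protein numbered, on chromosome 6, 57.6 per Mb for NIN and 15.8 per Mb for LSH1.

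**Figure D2:**
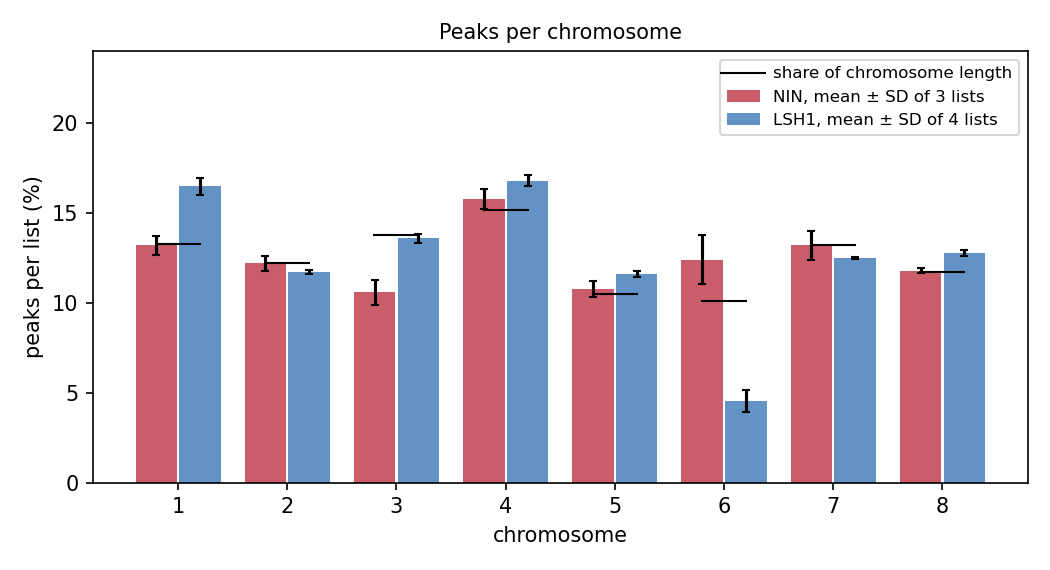
Share of peaks (%) on each of the 8 chromosomes, as mean and SD of the NIN and of the LSH1 lists; black marks give each chromosome's share of total length. On chromosome 6 the NIN mean is 12.4% and the LSH1 mean 4.54%.

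Lists of the same protein shared more peaks than lists of different proteins. Of the smaller list's peaks, 41.4% on average overlapped the other list within LSH1 (6 pairs, 35.5 to 47.8%), 36.0% within NIN (3 pairs, 20.4 to 48.5%) and 7.87% between the proteins (12 pairs, 3.42 to 15.3%). Random placement on the same chromosomes gave 4.51%, 13.5% and 9.05%. The mean within proteins exceeded that between proteins by 31.8 percentage points (one-sided exact permutation p = 0.0286). LSH1 lists agreed best at their beginning: 50.8% of the first 5000 peaks were shared within LSH1, against 10.2% within NIN and 1.26% between proteins. These peaks are 19.9 to 26.7% of the LSH1 lists but 35.7%, 17.3% and 5.94% of NIN replicates 1 to 3, so list length enters the contrast between NIN and LSH1. The order of the shared peaks correlated with a mean Spearman rho of 0.560 within LSH1 and 0.113 within NIN. These correlations are across peaks, which are not independent replicates.

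**Figure D3:**
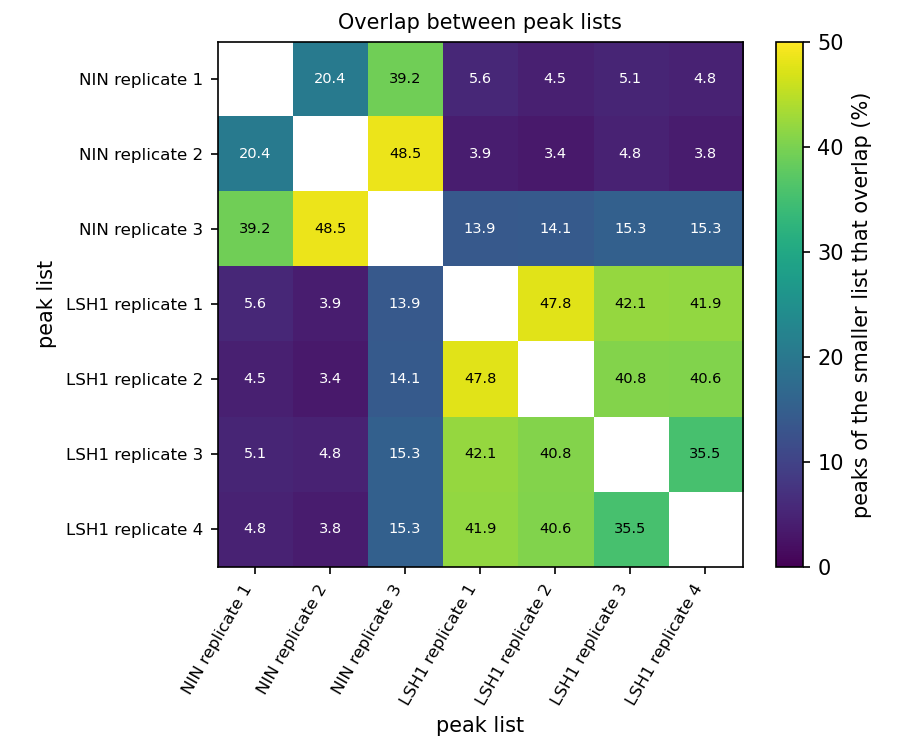
Overlap of each pair of the 7 peak lists, as the share (%) of the smaller list's peaks that overlap the other list by at least 1 bp. Pairs within LSH1 range from 35.5 to 47.8%, pairs within NIN from 20.4 to 48.5% and pairs of different proteins from 3.42 to 15.3%.

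Position in the list separated the proteins further. In the first 20% of the LSH1 lists, 90.8% ± 3.65 of peaks (SD, n = 4) overlapped another LSH1 list and 51.7% ± 1.99 lay in a gene-end window. In the last 20% these shares were 37.5% ± 2.58 and 42.4% ± 1.93. In the NIN lists, 50.3% ± 14.2 of the first 20% (SD, n = 3) and 34.6% ± 19.7 of the last overlapped another NIN list. The NIN gene-end share was 23.5% ± 2.90 in the first 20% and 27.5% ± 2.59 in the last, and it was lower in the first 20% of each of the 3 lists.

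**Figure D4:**
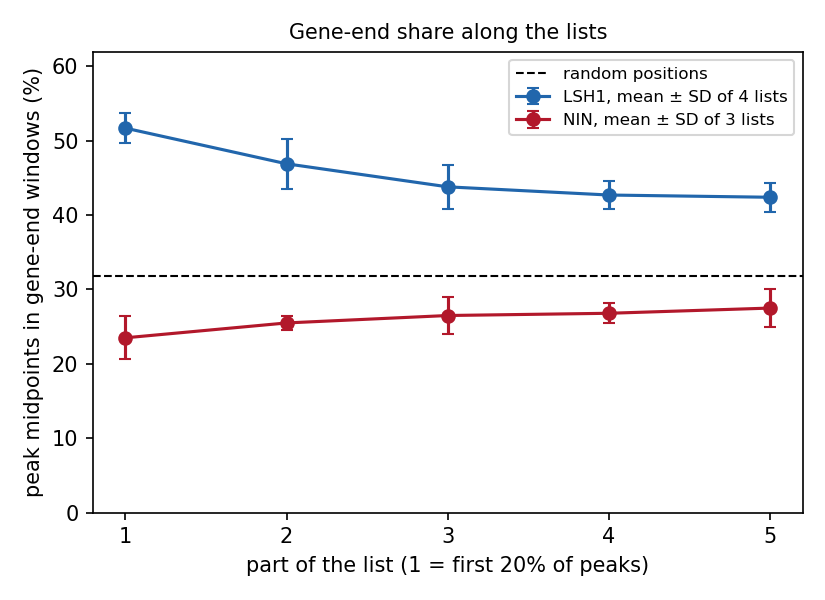
Share of peak midpoints (%) in gene-end windows in 5 successive parts of the list with 20% of the peaks each, from the first peaks listed (1) to the last (5), as mean and SD of the NIN and LSH1 lists; the dashed line is the share of random positions. The LSH1 mean runs from 51.7 to 42.4% and the NIN mean from 23.5 to 27.5%.

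Regions with peaks in at least 2 lists of a protein were called reproducible. LSH1 had 16713 such regions, 3.41 times the 4899 expected from random placement, and 4626 were in all 4 lists where 7.42 were expected. NIN had 17228, 2.39 times the 7218 expected, and 2092 were in all 3 lists where 233 were expected. Of the NIN regions, 65% lay over 2000 bp from coding genes and 22.2% had their midpoint in a gene-end window; for LSH1 the shares were 32.6% and 48.7%. The NIN number rested on single lists: it was 2840 without replicate 3 and 5341 without replicate 2.

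Regions in all lists of 1 protein and in no list of the other numbered 1718 for NIN and 3788 for LSH1. The NIN number was 11297 without NIN replicate 1 and 4446 without NIN replicate 2. Only 27 regions were in all 7 lists. The 5 LSH1 regions in all 4 lists with the best mean place, leaving out those within 5000 bp of rRNA genes, were 3816 to 6349 bp wide. The first, on chromosome 2 at 31051486 to 31057834, lay 9344 bp from the nearest coding gene, LOC25488411. The next 4 overlapped genes: LOC11419593 (chromosome 1, 56387515 to 56391577), LOC112417027 (chromosome 8, 40168196 to 40172271), LOC25500797 (chromosome 8, 10768349 to 10772852) and LOC25489462 (chromosome 3, 37193181 to 37196996). By the same rule, the best-placed NIN region lay on chromosome 3 at 33284986 to 33285753, 6071 bp from LOC25489229. The second, on chromosome 8 at 22129098 to 22129783, was 103567 bp from the nearest coding gene. The third overlapped LOC112417792 (chromosome 5, 23498529 to 23498855). The fourth (chromosome 7, 6621653 to 6623709) lay 521 bp from LOC120576944, and the fifth (chromosome 7, 14688429 to 14692294) 21299 bp from LOC112418345.

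Regions of the 2 proteins rarely coincided. Of the NIN regions, 472 (2.74%) overlapped an LSH1 region, and 481 LSH1 regions (2.88%) overlapped a NIN region. Random placement gave 5.95% and 6.42%, so that the observed NIN share was 0.461 times the expected one (permutation of region positions, p = 0.00990, the smallest that 100 placements can give). The direction was not common to the NIN lists. In each pair of lists the peaks of the smaller list were counted. Peaks of NIN replicate 1 overlapped each LSH1 list more often than placement (1.20 to 1.83 times). NIN replicates 2 and 3 are longer than the LSH1 lists, so LSH1 peaks were counted there. Peaks of each LSH1 list overlapped NIN replicate 3 less often (0.714 to 0.826 times). Peaks of LSH1 replicates 1, 2 and 4 overlapped NIN replicate 2 less often (0.694 to 0.838 times), and those of LSH1 replicate 3 more often (1.09 times). By the same permutation of positions, the ratio without NIN replicate 3 was 0.956 (p = 0.307), with the first 5000 peaks of each list it was 1.11 (p = 0.327), and with peaks reduced to midpoints within 100 bp it was 1.52 (p = 0.00990).

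Of 31728 coding genes, 7481 (23.6%) had the midpoint of an LSH1 region in a gene-end window and 3733 (11.8%) that of a NIN region. These are called target genes here, with no reference to expression. Random placement gave 5530 to 5886 genes for LSH1 and 5540 to 5842 for NIN. The proteins shared 473 target genes where 880.2 were expected from independent lists (odds ratio 0.435, two-sided Fisher's exact test, p = 2.49e-70; neighbouring genes are not independent). With the first 5000 peaks of each list the odds ratio was 0.786 (exact p = 0.413). Target genes with a region in all lists numbered 2561 for LSH1 and 474 for NIN, of which 12 were common. Their odds ratio was 0.293 (two-sided Fisher's exact test, p = 5.98e-07, with the same limit for neighbouring genes).

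The 10 genes with the best mean place among those with an LSH1 region in all 4 lists were LOC112417027, LOC25480017, LOC25500797, LOC25489462, LOC120580582, LOC25490247, LOC25499388, LOC11421532, LOC25493897 and LOC112421022. For NIN they were LOC25480017, LOC120580582, LOC120576944, LOC112422817, LOC120579669, LOC25488479, LOC11425534, LOC112417294, LOC11412439 and LOC25491003. LOC25480017 and LOC120580582 stood in both and lie within 5000 bp of annotated rRNA genes. Among genes at LSH1-only regions LOC25490247 came first, with a region on chromosome 3 at 56187555 to 56190523 and a mean place of 0.105% of the list. Among genes at NIN-only regions LOC112422817 came first, with a region on chromosome 6 at 30336483 to 30339987 and a mean place of 2.27%. The gene table gives no product for these genes.

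Of the nodulation genes fixed before the data were examined, 16 of 52 could be matched by name, and 6 were LSH1 target genes while 2 were NIN target genes. The LSH1 targets were NSP1 (a GRAS transcription factor of nodulation signalling), NOOT1 and NOOT2 (BTB-ankyrin co-regulators that maintain nodule identity), DMI3 (the calcium- and calmodulin-dependent kinase), IPD3 (its transcription factor partner) and ENOD20 (an early nodulin). The fixed identifier of ENOD20 names a different chromosome from that of the gene matched by symbol, so this match is in doubt. The NIN targets were ENOD11, an early nodulin, and VPY (vapyrin, needed for infection). Against 23.6% and 11.8% of other genes, the odds ratios were 1.95 for LSH1 (two-sided Fisher's exact p = 0.234, adjusted p = 0.703) and 1.07 for NIN (p = 1.00, adjusted p = 1.00), and neither passed the test. With windows of 1000 bp outside gene ends the LSH1 odds ratio was 2.83 (exact p = 0.0466, unadjusted). Without LSH1 replicate 2 it was 2.79 (exact p = 0.0491, unadjusted). With whole genes and 3000 bp to each side it was 1.17 (exact p = 0.794), and the share was 1.12 times that of lists matched on length (permutation p = 0.912). For NIN it was 0 without NIN replicate 3 and 0.742 without replicate 1.

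Single regions at these genes differed in how often they recurred. At NSP1 (LOC11434050) an LSH1 region on chromosome 8 at 7300857 to 7302174 overlapped the gene, was in 4 of 4 lists and had a mean place of 2.50% of the list; another in the gene (7302403 to 7302868) was in 2 lists with 72.4%. The DMI3 region (chromosome 8, 16667419 to 16667955) was in 4 lists with a mean place of 35.7%, and the IPD3 region (chromosome 5, 11125910 to 11126534) in 3 lists with 44.9%. At NOOT1 (LOC11417633) the region that overlapped the gene (chromosome 7, 42203427 to 42204208) was in 3 lists with a mean place of 40.4%. The best-placed LSH1 region near NOOT1 (chromosome 7, 42217345 to 42218513) lay 10074 bp from the gene, was in 4 lists and had a mean place of 2.97%. Within 20 kb NOOT1 had 11 LSH1 regions and 1 NIN region. NOOT2 (LOC25483282) had 3 LSH1 regions in the gene, each in 2 lists, and 4 NIN regions outside it. ENOD11 had 2 NIN regions, each in 2 of 3 lists: 1 on chromosome 3 at 4701821 to 4702295 that overlapped the gene, with a mean place of 56.2%, and 1 at 4698951 to 4700434, 1126 bp from it, with 27.8%. The NIN region of VPY (chromosome 6, 10273255 to 10274960) lay 765 bp from the gene and was in 2 lists, with a mean place of 53.8%.

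Further lists were drawn from the names in the gene table, after the table but before any of their values had been seen. Of 8 nodulins and leghemoglobins, 4 were NIN targets (ENOD11, MtN13 and the leghemoglobins LB1 and LB6; odds ratio 7.51, two-sided Fisher's exact p = 0.00905, adjusted p = 0.109) and 2 were LSH1 targets (ENOD20 and MtN13; odds ratio 1.08, p = 1.00). The NIN call did not pass the adjustment over 12 tests, none of the 6 NIN regions at these 4 genes was in all 3 NIN lists, and without NIN replicate 3 the odds ratio was 0. With windows of 1000 bp outside gene ends it was 15.3 (exact p = 8.18e-04) and passed the adjustment. Of 8 lectins, 3 were NIN targets (Lec6, Lec9 and Lec11; odds ratio 4.50, exact p = 0.0578, adjusted p = 0.347) and 0 were LSH1 targets (p = 0.211). Lec6 and Lec9 shared 1 NIN region, and without NIN replicate 3 the lectin odds ratio for NIN was 0. Of 6 genes of mycorrhizal symbiosis, 2 were LSH1 targets (D27, a strigolactone synthesis enzyme, and STR2, an ABC transporter of arbuscules; odds ratio 1.62, exact p = 0.631) and 1 was a NIN target (RAM2, a glycerol-3-phosphate acyltransferase; odds ratio 1.5, p = 0.528). The STR2 region (chromosome 5, 13141028 to 13142311) was in 4 LSH1 lists with a mean place of 10.6%. Of 8 lignin and saponin enzymes, 3 were LSH1 targets (CAD1, CAD2 and CYP72A67; odds ratio 1.95, exact p = 0.403) and 1 a NIN target (CYP72A68; odds ratio 1.07, p = 1.00). CAD1, a cinnamyl alcohol dehydrogenase, had 3 LSH1 regions in the gene, the first of them in 4 lists with a mean place of 0.694% (chromosome 1, 52401907 to 52403018). Of 4 hormone genes, DELLA2, a repressor of gibberellin response, was an LSH1 target with 2 regions in 4 lists each, 1 that overlapped the gene (chromosome 8, 37952578 to 37954670, mean place 16.2%) and 1 at 1064 bp from it (37954830 to 37956660, 2.84%; odds ratio of the list 1.08, exact p = 1.00), and 0 were NIN targets (p = 1.00). With windows of 2000 bp no list passed the adjustment for either protein.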

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

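All explanations weighed here were tested after the patterns had been seen, except the one on distance to genes for the overlap of the proteins.

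The list of NIN replicate 3 held 15 peaks on the mitochondrial sequence, above the 3 that a count of 0 allows, while each of the other 6 lists held 0. It also held 638 peaks outside the 8 chromosomes, against 9 to 47 in the others. These peaks entered no gene comparison. The list of NIN replicate 3 is also the longest, with 84178 peaks against 14021 to 28825 in the others. Neither count was scaled to list length, so list length enters both contrasts. None of 9 measures had an outlying list among the 4 LSH1 lists; groups of 3 lists were not tested, and chance alone marks about 1 in 20 groups.

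NIN peaks lay away from coding genes. The large list of NIN replicate 3 does not account for the low gene-end share. The higher gene-end share of the other 2 NIN lists was 27.5%, below the 31.8% of random positions by more than the SD of 1.71 between NIN lists. By other measures NIN replicate 1 was nearer to random positions. Inside coding genes lay 30.7% of its peaks, 24.5% of those of replicate 2 and 30.5% of random positions. Over 2000 bp from coding genes these shares were 50.4%, 58.4% and 46.8%. Dilution of gene-near sites by false peaks low in the lists would put such sites first if the order follows peak strength. The gene-end share of the first 20% of peaks minus that of the last 20% was -3.97 percentage points on average. The difference was negative in each of the 3 lists. The order cannot decide this: its measure is not named, and the order of shared peaks correlated weakly within NIN (mean Spearman rho 0.113). Dilution therefore stays open. Gene-poor stretches are not the whole account: coding genes with a NIN region within 500 bp were 0.627 times as many as after shifts of 20 to 100 kb, below all 100 shifts. Repeats, base composition and the control libraries were not tested and remain open, as does a biological difference between NIN and LSH1.

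NIN and LSH1 regions overlapped less often than random placement. Differences in chromosome region or distance to genes do not account for all of it, since the overlap was 0.640 times that of regions shifted by 20 to 100 kb and, among NIN regions over 2000 bp from coding genes, 0.633 times that of shifts kept in the same context. For regions, the pattern rested on the list of NIN replicate 3: without it the ratio was 0.956 (permutation of positions, p = 0.307). Few overlaps were not limited to that list. Peaks of NIN replicate 2 alone overlapped LSH1 regions 0.552 times as often as placement and 0.724 times as often as shifts, below all 100 of each, while peaks of replicate 1 were at 1.11 times placement, inside its range, and 1.18 times shifts, above all 100. The odds ratio of target genes without NIN replicate 3 was 0.422. The direction for regions also turned with the settings. Their overlap was 1.11 times placement with the first 5000 peaks of each list and 1.52 times with midpoints within 100 bp. Since few overlaps were not seen for NIN replicate 1, avoidance between the proteins is not established by these data, and why the lists differed stays open.

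Peaks common to all 7 lists were led by regions in 1 stretch of chromosome 5. Of the 10 best-placed such regions, 9 lay there between 23802279 and 23927255, within 5000 bp of annotated rRNA genes, and the other lay on an unplaced sequence. Their mean places were at most 0.188% of the list, and the next region stood at 7.07%. Only 1 of the 9 overlapped an rRNA gene, and the others lay 504 to 4977 bp from one. Called regions were few at rRNA genes in general. Of 1407 such genes, 4 had a NIN region within 500 bp (0.0296 times placement, below the 72 to 210 genes of 100 placements). An LSH1 region lay at 1 of them (0.0131 times, below 29 to 129). Against shifts the NIN count was 0.0518 times, below the 38 to 113 genes of 100 shifts, and the LSH1 count 0.433 times, within 0 to 9. Few called regions do not exclude signal at repeated genes. Whether repeats in this stretch are the source stays open, because copy number and sequence were not analysed, and binding there was not excluded. Without regions near rRNA genes the overlap of the proteins was 0.454 times random placement, an alternative chosen after seeing the data. For regions in all lists of each protein it went from 0.365 (19 of 2092 regions) to 0.196 (10 of 2080).

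For the regions specific to a protein, 1 of 35 splits of the 7 lists gave as many regions, the real one with 5506, and the highest of the others gave 1505. The exact permutation p was thus 0.0286, the smallest that 35 splits can give. This makes chance assignment of lists to proteins unlikely for this count but does not exclude it. The count uses the same list overlaps as list agreement and is not separate support. The LSH1 set carried the count, with 3788 against at most 218 in 4 lists of another split. The NIN set was nearer to another split, with 1718 against 1433 for LSH1 replicates 1, 2 and 4.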

How the results depend on the processing

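The alternatives were chosen before the data were examined, except leaving out regions near rRNA genes and those for chromosome 6. With regions in at least 2 lists, leaving out those near rRNA genes moved none of the 4 results it was run on across the threshold or by over 1.5 times. With regions in all lists, shared regions went from 0.365 to 0.196 times placement. The chromosome 6 difference was 7.89 points, 9.36 with the first 5000 peaks and 7.12 to 8.44 with a list left out. The filter on −log10 q and the motif tests were not run. With 1 list left out, the exact tests cannot give a p under 0.0667 or 0.100, so the loss of significance there says nothing about stability. The difference in gene-end share stayed between -20.3 and -18.6 points, that in list agreement between 29.6 and 33.9 points and the odds ratio of target genes between 0.385 and 0.492. With 1 list left out, NIN reproducible regions ranged from 2840 to 17228, NIN-only regions from 1783 to 11297, both protein-only sets together from 5976 to 15166, shared regions from 0.350 to 0.956 times placement and the ratio of peak numbers from 0.934 to 2.29.

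Whether replicate numbers pair the lists was not settled. Correlations of same-numbered NIN and LSH1 lists over 428 bins of 1 Mb were 0.314, 0.112 and -0.0418. Those of different-numbered lists ranged from -0.369 to 0.293, so pairing was neither shown nor excluded. With a replicate block over 3 pairs the gene-end difference was -19.9 points (exact sign-flip p = 0.25, the smallest such a test can give) and the ratio of peak numbers 1.49 (p = 0.750). The block was run on these 2 results, which have 1 value per list.

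With peaks required in all lists, reproducible regions were 2092 for NIN and 4626 for LSH1. With the first 5000 peaks, which cut the NIN lists at unequal depth (5.94 to 35.7% of the list), they were 1185 and 4447, the protein-only sets 119 for NIN and 1601 for LSH1 (1720 together), shared regions 1.11 times placement and the odds ratio of target genes 0.786. With midpoints within 100 bp, NIN regions were 6987 and shared regions 1.52 times placement. The cause was not tested.

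Gene lists were small. The nodulation list's odds ratio for NIN was 0 with all lists and with the first 5000 peaks, 0.513 with whole genes, 0.632 times lists matched on length, and 0 to 1.52 with a list left out. For LSH1 it was 0.775 with the first 5000 peaks, 2.83 with windows of 1000 bp, 1.17 with whole genes, and 1.95 to 2.79 with a list left out. With windows of 1000 bp 1 of the 12 list tests passed the adjustment, nodulins and leghemoglobins for NIN (odds ratio 15.3, unadjusted exact p = 8.18e-04). For this list the odds ratio was 0 with all lists or the first 5000 peaks for NIN, 0 with the first 5000 for LSH1, and 0 to 7.59 for NIN with a list left out. For NIN, lectins and lignin and saponin enzymes were at 0 with all lists and the first 5000 peaks, and the enzymes also with windows of 1000 bp; with a list left out these ranged from 0 to 6.69 and 0 to 1.59, and mycorrhizal genes from 0 to 4.55. With whole genes all 4 hormone genes were LSH1 targets, so the odds ratio was not finite. Their share was 2.86 times that of lists matched on length (permutation p = 0.0304). Lectins for NIN were at 5.99 with whole genes (exact p = 0.0151), 2.89 times matched lists (permutation p = 0.0264) and 6.69 without NIN replicate 1 (exact p = 0.0228). Mycorrhizal genes for NIN were at 25.1 with the first 5000 peaks (exact p = 0.0467), a value that rests on 1 target among 6 genes. These p-values are unadjusted.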

Other observations

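The tests in this part were chosen after seeing the data. LSH1 regions were frequent at tRNA and snRNA genes. Of 746 tRNA genes, 97 had an LSH1 region within 500 bp, 1.88 times random placement and 1.61 times shifts of 20 to 100 kb (42 to 80 genes in 100 shifts). NIN regions lay at 19 tRNA genes, 0.322 times placement and 0.446 times shifts (29 to 59 genes). Of 210 snRNA genes, 36 had an LSH1 region, 2.08 times shifts (9 to 28 genes), and 12 had a NIN region, 0.864 times shifts (7 to 21 genes). At 971 snoRNA genes LSH1 regions were not frequent: 29 genes had one, 0.459 times placement and 0.798 times shifts (21 to 59 genes), against 80 for NIN, 1.00 times placement and 0.889 times shifts (67 to 119 genes). Of 1562 pseudogenes, 165 had an LSH1 region, 0.634 times placement and 0.645 times shifts. A NIN region lay at 293, which is 1.14 times shifts (220 to 285 genes) but 1.02 times placement (254 to 352 genes).

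LSH1 regions were dense around NOOT1. Its 11 regions within 20 kb compare with a median of 2 over all coding genes, and 0.410% of coding genes had as many. NOOT1 was singled out after its values were seen. Over the 16 matched nodulation genes the mean was 2.75 regions, against 2.12 over all genes (permutation test with 10000 random lists, two-sided p = 0.284), so the list as a whole did not stand apart. For NIN the means were 1.31 and 1.55 (permutation p = 0.684).

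Of LSH1 regions in all 4 lists on the chromosomes, 258 of 4620 (5.58%) were wider than 2000 bp, and 51.2% of these had their midpoint in a gene-end window. Of NIN regions in all 3 lists, 436 of 2090 (20.9%) were wider than 2000 bp, and 16.1% had it there. The NIN number rested on replicate 3: 397 of the 436 overlapped a peak of that list wider than 2000 bp, against 0 for replicate 1 and 2 for replicate 2. Without replicate 3, 4 of 2837 regions in both other lists were that wide.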
